A study of Homo sapiens with 2 samples.

How the data were processed

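RNA was extracted from HGC-27 cells that carried a non-targeting shRNA or an shRNA against DDX5, and 1 library per condition was sequenced with Illumina chemistry, per the labels' protocols. The authors deposited 1 table for the series, with FPKM (fragments scaled to transcript length and library depth) in 1 column per library, per the file headers. Values are printed with 2 decimals, and no listed gene is at 0 in both columns. The submitters' processing notes name HISAT, Bowtie2, RSEM 1.2.8 and the human build hg19, without their roles or order. The strand setting, the annotation and any filter are not given in the sources used here. FPKM fixes neither the composition of a library nor the division of reads between near-identical genes, and RSEM divides shared reads by estimation, so copies of a gene can exchange values.

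Columns were assigned to conditions by the sample titles. The table holds 16021 rows keyed by Entrez gene numbers or by models named BGI_novel. RefSeq gene names (assembly GRCh38.p14) matched 15289 rows, 701 rows were BGI_novel models and 31 were other unmatched numbers. Because the reference build differs from hg19, no coordinates are given, and the reference served for names, neighbouring genes, transcript length, GC content and shared sequence. Length and GC content came from the longest protein-coding GENCODE v29 transcript of each Entrez number, with a match for 98.0% of genes past the filter. Shared sequence was the percentage of 50-base windows, taken every 10 bases, that also occur in a protein-coding transcript of another gene.

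Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For each gene the log2 ratio of FPKM + 1 was taken, DDX5 shRNA over non-targeting shRNA, which understates the difference of genes with low values and is the scale of every log2 ratio given. Statements that a gene was at least 2-fold higher, at least 2-fold lower or 2-fold apart, and all counts of such genes, also refer to FPKM + 1 (a log2 ratio of 1 or more, or of -1 or less), so some weakly expressed genes pass 2-fold on the deposited FPKM without being counted. A fold given as a value for a single gene is the ratio of the deposited FPKM. Genes with a mean of 1 FPKM or more over both libraries (11413) entered counts and list medians. With 1 library per group no test was run. For each gene list the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn with replacement from the same of 20 bins of mean expression. The central 95% of those medians describes these libraries and is not a test across cultures. Lists overlap in part.

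Before the data were examined, 32 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The rule names DDX5, the 15 highest and 15 lowest log2 ratios at a mean of 5 FPKM or more, up to 4 members per list with the largest absolute ratio among its members at a mean of 5 FPKM or more (1 or more where fewer than 2 members reach 5), up to 2 members nearest the list median, and always DDX17, MYC, CCND1, CDKN1A, MTOR and SQSTM1. Genes outside the rule are marked as chosen after their values were seen, or serve as copies, neighbours or markers for a stated check (SERF1B, ESRP2, FSBP, EPCAM). Some genes that the rule names are not reported here. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, rescaling to the same total, and centring on the median or on a mean trimmed by 30% at each end. Correction for length and GC content, in 10 by 10 bins, leaving out members shared with the ATF4 list, and leaving out ESRP1 were added after the data were seen. A gene's spread was the robust SD of log2 ratios in its expression bin, and a list's spread was the SD of its matched random medians.

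Depth is not stated in the table. For short genes with 1 annotated transcript, FPKM times length should fall on whole steps worth 1 fragment. At the best-fitting step 73.3% of 116 genes in the non-targeting library and 71.4% of 105 genes in the DDX5 shRNA library fell within 0.15 of a whole step. For a step fixed beforehand, 30% would by chance. The step and the length correction were chosen for the best fit to these same genes, so the chance level is higher here and was not measured. The steps correspond to about 1.52e+07 and 1.47e+07 fragments, with transcript lengths shortened by 150 bases. Fragment numbers given for genes used the full length of the longest transcript, so they are approximate and can be too high.

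The procedure was tested on simulated data for this comparison, with all 16021 genes, 200 of them changed, with a noise SD of 0.33 per library on the log2 scale and 1000 matched random lists. Of genes made 4-fold different, 98% came out at least 2-fold apart in the right direction, and of those made 2-fold different, 35%, while 1.83% of 11229 unchanged genes did. Of 200 unshifted lists of 30 genes, 2% fell outside the central 95%, and all of the lists shifted by 0.5 fell above it (100%). These lists were drawn at random and each gene had its own noise, so a low share outside was built in. Lists of genes that vary together were not simulated, and the noise SD was a setting, not a spread measured between cultures.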

Results

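Gene expression was measured by RNA sequencing in HGC-27 cells, a human gastric cancer line, after lentiviral transduction with an shRNA against DDX5 or with a non-targeting shRNA. DDX5 is a DEAD-box RNA helicase that takes part in transcription, splicing and microRNA processing. Puromycin was added 48 h after transduction, and the cells were collected after 1 week of selection. Each condition was represented by 1 library, so the comparison set 2 libraries side by side and allowed no p-value, standard error or count of changed genes. The table listed 16021 genes or gene models as FPKM, of which 15159 were above 0 in the non-targeting library and 15356 in the DDX5 shRNA library. Steps between the low FPKM values of short genes corresponded to about 1.52e+07 counted fragments in the non-targeting library and 1.47e+07 in the DDX5 shRNA library, as estimates from 116 and 105 genes. At that depth, each of the 29 genes with a known transcript length among the 15 highest and 15 lowest ratios came to about 481 fragments or more in its higher library. These numbers use full transcript lengths and can be too high. The lowest was that of SERF1A, whose sequence is largely shared with a copy. The spread between cultures was not measured.

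The first question was whether the DDX5 transcript was lower in the cells that carried its shRNA. DDX5 (Entrez gene 1655) stood at 170.5 FPKM in the non-targeting library and at 50.78 FPKM in the DDX5 shRNA library, which is 29.8% of the control level and a log2 ratio of -1.73 on FPKM + 1 (3.36-fold lower). It ranked 13 from the lowest ratio among 8545 genes with a mean of 5 FPKM or more. The mRNA of its closest paralog, DDX17, stood at 74.58 and 100.21 FPKM, a log2 ratio of 0.42. Across 11413 genes with a mean of 1 FPKM or more, the Spearman correlation of both libraries was 0.945 (genes are not independent replicates). Of those genes, 478 were at least 2-fold higher and 258 at least 2-fold lower in the DDX5 shRNA library on FPKM + 1, the scale of all such counts here, and 10677 lay within 2-fold. With both libraries rescaled to the same total FPKM, which shifted the median of all genes by -0.10 on the log2 scale, there were 370 genes at least 2-fold higher and 374 genes at least 2-fold lower. Centring on the median gave 442 and 281, and centring on a trimmed mean 463 and 262. The excess of higher genes was absent under 1 of these 3 scalings, the same total. Before rescaling, total FPKM was 549129 in the non-targeting library and 594757 in the DDX5 shRNA library. The fixed list of cytosolic ribosomal protein genes made up 27.5% and 32.9% of it. Same-total values of other genes therefore depend in part on that list. The number of 2-fold differences that 2 cultures of the same cells would show was not measured.

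**Figure D1:**
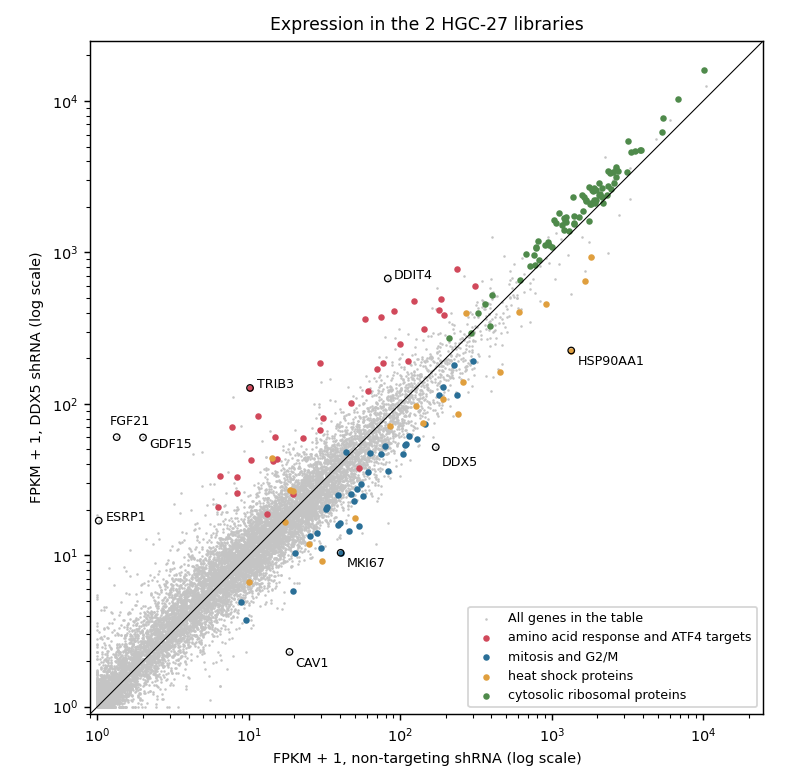
FPKM + 1 of each gene in the non-targeting library (x axis, log scale) against the DDX5 shRNA library (y axis, log scale), with 4 of the fixed gene lists coloured, 9 genes circled and the line of equal expression drawn. ATF4 targets such as TRIB3 lie above the line, while DDX5, mitotic genes and HSP90AA1 lie below it.

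Of the 15 genes with the highest ratios, 3 belonged to the fixed list of amino acid response and ATF4 targets (TRIB3, CHAC1 and DDIT3). FGF21, a secreted metabolic hormone, stood at 0.34 FPKM, worth about 7 fragments, in the non-targeting library and at 59.26 FPKM in the DDX5 shRNA library. GDF15, a secreted stress cytokine, stood at 1 and 58.97 FPKM, a log2 ratio of 4.91. INHBE, an inhibin beta subunit, was 13.9-fold higher. TRIB3 and CHAC1, both induced by the transcription factors ATF4 and CHOP, were 13.8-fold and 10.3-fold higher, and DDIT3, which encodes CHOP, was 7.86-fold higher. CTH, a transsulfuration enzyme that makes cysteine, was 8.81-fold higher. DDIT4, an inhibitor of mTOR signalling, stood at 81.72 and 671.4 FPKM, and TXNIP, which restrains glucose uptake, at 14.33 and 127.83 FPKM. The glucocorticoid-inducible gene TSC22D3 was 15.9-fold higher, AKNA 12.2-fold, the kinase gene FYN 9.67-fold and the collagen gene COL15A1 9.48-fold. ESRP1, an epithelial splicing regulator, was listed at 0.02 FPKM, worth about 1 fragment, in the non-targeting library and at 15.92 FPKM in the DDX5 shRNA library. SERF1A was listed at 0 in the non-targeting library and at 17.32 FPKM in the other, but 97.3% of the 50-base windows of its transcript also occur in its copy SERF1B (46.03 and 42.59 FPKM), so its value depends on how reads were divided.

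Of the 15 genes with the lowest ratios, 3 belonged to the fixed mitosis list (MKI67, KIF20A and ASPM), 2 to the heat shock list (HSP90AA1 and HSPA1B) and 2 to the mesenchymal list (ACTA2 and TAGLN). CAV1, the main structural protein of caveolae, stood at 17.55 and 1.3 FPKM, a 13.5-fold lower level in the DDX5 shRNA library, and its partner CAVIN1 was 4.25-fold lower. ACTA2 and TAGLN, smooth-muscle-type actin cytoskeleton genes, were 5.37-fold and 4.56-fold lower. HSP90AA1, the inducible cytosolic HSP90, was 6.01-fold lower, at 1345 and 223.95 FPKM. The proliferation marker MKI67 was 4.20-fold lower, the mitotic kinesin KIF20A 3.55-fold and the spindle gene ASPM 3.83-fold. The mitosis-associated helicase gene ERCC6L was 4.12-fold lower, FAM111B 3.69-fold and the tubulin gene TUBB4B 3.28-fold. HSPA1B, a heat-inducible HSP70 gene that shares 71.4% of its 50-base windows with HSPA1A, was 3.63-fold lower. LOC102724594, 6.33-fold lower, shares 93.9% of its windows with the splicing factor gene U2AF1 (136.15 and 96.25 FPKM), and the sum of both was 204.62 and 107.06 FPKM. The unannotated model BGI_novel_G001267 was 4.18-fold lower.

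**Figure D2:**
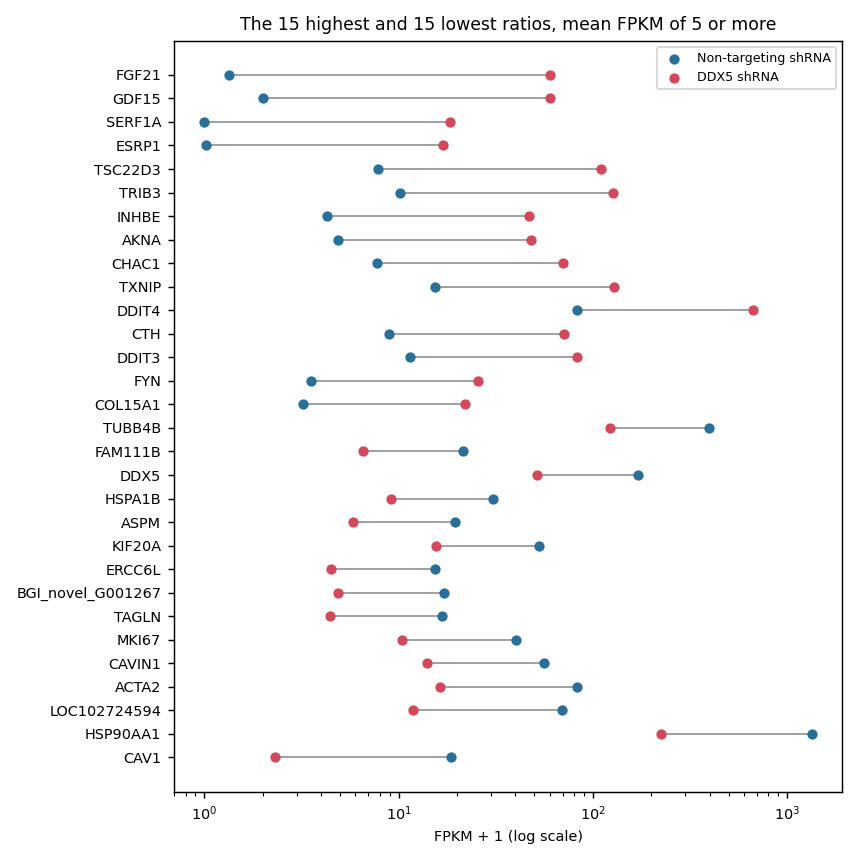
FPKM + 1 (x axis, log scale) of the 15 genes with the highest and the 15 with the lowest ratio among genes with a mean of 5 FPKM or more, with 1 point per library. The points of FGF21, GDF15 and SERF1A lie farthest apart among the higher genes, and those of CAV1 and HSP90AA1 among the lower ones.

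Gene lists fixed beforehand were then compared with 10000 random lists of the same size and expression level, as a description of these libraries. The amino acid response and ATF4 target list stood apart most: 28 of its 34 measured members were at least 2-fold higher in the DDX5 shRNA library, and its median log2 ratio of 1.44 exceeded all 10000 matched lists. Its members cover asparagine and serine synthesis, amino acid transport, tRNA charging and the CHOP branch. TRIB3, CHAC1, DDIT3 and VEGFA had the largest ratios, from 3.64 to 2.65 on the log2 scale, and GARS1 (185.86 and 491.53 FPKM) and STC2 (14.3 and 41.94 FPKM) were typical of the list. The single member below 0 was ALDH18A1, a proline synthesis enzyme, at 52.65 and 36.41 FPKM (chosen after its value was seen). By contrast, the endoplasmic reticulum chaperone list of 23 genes had a median of 0.19 (0.075 at the same total), within the central 95% of matched lists. It also holds genes that are not chaperones, such as the transcription factor gene XBP1. Of its members, 14 had a ratio above 0 and 9 below. HERPUD1 (28.18 and 94.87 FPKM), DNAJB9 (3.52 and 12.19 FPKM), XBP1 (71.41 and 204.26 FPKM) and SEL1L (19.19 and 55.14 FPKM) were at least 2-fold higher. SDF2L1, HSP90B1 and PDIA4 (chosen after their values were seen) had the lowest log2 ratios, at -0.84, -0.68 and -0.67. HYOU1 was typical at 106.98 and 122.08 FPKM.

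Hypoxia targets were also higher, with 8 of 27 members at least 2-fold higher on FPKM + 1, none 2-fold lower (1 at the same total, CA12, chosen after its value was seen), and a median of 0.60 that exceeded all 10000 matched lists. DDIT4, VEGFA, P4HA2 and PDK1 led, with log2 ratios of 3.02, 2.65, 2.39 and 1.84, and KDM3A was typical at 19.59 and 30.1 FPKM. The 22 glycolysis genes had a median of -0.11, within the central 95% of matched lists. Among them, PDK1, which limits pyruvate use in mitochondria, stood at 2.01 and 9.75 FPKM, whereas PKM (715.81 and 345.98 FPKM) and LDHA (841.91 and 479.27 FPKM), which act at the end of glycolysis, had log2 ratios of -1.05 and -0.81. Nuclear oxidative phosphorylation genes had a median of 0.07 over 43 members, which was -0.047 at the same total, with none of them 2-fold apart on FPKM + 1. Of the 13 mitochondrially encoded genes of the fixed list, 0 were analysed here.

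Cell division genes were lower as a group. In the mitosis and G2/M list, 17 of 37 members were at least 2-fold lower and none 2-fold higher, and the median log2 ratio of -0.97 lay below all 10000 matched lists. MKI67, KIF20A, ASPM and DLGAP5 had ratios from -1.96 to -1.66, and the topoisomerase gene TOP2A was typical at 144.07 and 72.04 FPKM. In the DNA replication and G1/S list, 14 of 42 members were at least 2-fold lower, none 2-fold higher, and the median was -0.73, again below all 10000 matched lists. The flap endonuclease gene FEN1 stood at 97.84 and 32.42 FPKM, MCM10 at 24.81 and 8.57 FPKM, MCM4 at 84.88 and 31.2 FPKM, and UHRF1 at 42.82 and 16.03 FPKM. CCND1, which encodes cyclin D1, lay at 85.44 and 66.86 FPKM, a log2 ratio of -0.35. MYC stood higher in the DDX5 shRNA library, at 176.77 and 290.13 FPKM, a log2 ratio of 0.71. CDKN1A, the p21 cell cycle inhibitor, stood at 3.72 and 11.26 FPKM, a log2 ratio of 1.38.

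Helicases, splicing factors and ribosome biogenesis factors were lower as groups. Among 42 other DEAD-box and DExH helicases, 36 had a ratio below 0 and the median of -0.45 lay below all 10000 matched lists. DHX9, DDX39A, DDX23 and DDX46 were the members at least 2-fold lower, with log2 ratios of -1.21, -1.10, -1.09 and -1.04. Splicing factors had a median of -0.49 over 40 members, below all 10000 matched lists, led on the lower side by HNRNPD (367.95 and 151.85 FPKM) and HNRNPM (278.5 and 118.21 FPKM). HNRNPA1 and, chosen after its value was seen, SRSF4 were the remaining members at least 2-fold lower, with log2 ratios of -1.02 and -1.01, and ESRP1 was the only member at least 2-fold higher. At the same total, 7 splicing factors were at least 2-fold lower. Ribosome biogenesis factors had a median of -0.48 over 43 members, below all 10000 matched lists. UTP20, RRP1 and LYAR were the members at least 2-fold lower, with log2 ratios of -1.41, -1.09 and -1.09. In the microRNA processing list the median was -0.21 over 18 members at percentile 4.05, with a range of 2.22 to 4.61 over 8 alternatives, and HNRNPA1 was the only member 2-fold apart on FPKM + 1. DGCR8, a subunit of the Microprocessor, stood at 15.87 and 8.92 FPKM. Cytosolic ribosomal protein genes went the other way, with 75 of 78 above 0 (68 at the same total) and a median of 0.33 that exceeded all 10000 matched lists, although none reached 2-fold. RPL12 and RPL3 led with log2 ratios of 0.77 and 0.74, and the list's share of total FPKM was 27.5% in the non-targeting library and 32.9% in the DDX5 shRNA library. In the same pair of libraries, the 10% of genes with the shortest transcripts had a median of 0.13, and the 10% with the longest 0.0017.

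Heat shock proteins were among the lowest lists, with 8 of 21 members at least 2-fold lower and a median of -0.89, below all 10000 matched lists. HSP90AA1, HSPA1B and HSPH1, a co-chaperone of HSP70, had log2 ratios of -2.58, -1.74 and -1.51. The small heat shock protein gene CRYAB was the member at least 2-fold higher, at 13.29 and 42.62 FPKM. Cholesterol synthesis genes had a median of -0.53 over 24 members, below all 10000 matched lists. ACAT2 and HMGCS1 had ratios of -1.33 and -1.29, DHCR7 and FDPS (chosen after their values were seen) were also at least 2-fold lower at -1.09 and -1.04, and MVD was typical at 23.01 and 15.38 FPKM. TM7SF2, a sterol reductase, was the member at least 2-fold higher, at 5.18 and 17.76 FPKM.

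Autophagy and lysosome genes were slightly higher, with 31 of 40 members above 0 and a median of 0.24 at percentile 99.28 of matched lists. At the same total, 28 members were above 0 and the median was 0.14. GABARAP, a ubiquitin-like protein of the autophagosome, stood at 79.52 and 203.3 FPKM, and its relative MAP1LC3B at 31.91 and 62.68 FPKM. GABARAP and WIPI1, the latter chosen after its value was seen, were the members at least 2-fold higher on FPKM + 1, with log2 ratios of 1.34 and 1.37. SQSTM1, the p62 autophagy receptor, stood at 61.14 and 70.06 FPKM. Genes of the mTOR pathway had a median of 0.07 over 40 members (-0.038 at the same total), within the central 95% of matched lists, and MTOR itself stood at 16.79 and 16.16 FPKM. The members at least 2-fold higher were negative regulators or mTOR substrates: DDIT4, SESN2 (5.45 and 32.6 FPKM), EIF4EBP1 (161.38 and 428.64 FPKM) and SESN3 (4.31 and 11.15 FPKM). The p53 target list had a median of 0.14 over 29 members (0.047 at the same total), within the central 95%. Of its members, 17 had a ratio above 0 and 12 below, with 7 at least 2-fold higher and none 2-fold lower. GDF15, SESN2, PMAIP1 and CDKN1A led, with log2 ratios of 4.91, 2.38, 1.62 and 1.38. SESN2 is also a member of the ATF4 list. Without it, a setting apart from the 8 alternatives, the p53 median was 0.11 over 28 genes at percentile 77.51. With only members at a mean of 5 FPKM or more, the p53 median was 0.31 over 19 genes, at percentile 98.52, whereas the lowest percentile over 8 alternatives was 80.84. BCL2 family and caspase genes had a median of -0.047 over 25 members, within the central 95%. PMAIP1 and, chosen after their values were seen, BMF (1.59 and 5.17 FPKM) and HRK (0.65 and 2.81 FPKM) were its members at least 2-fold higher on FPKM + 1.

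Lists on cell identity and adhesion showed members moving both ways. Mesenchymal and EMT genes had a median of -0.02 over 29 members, within the central 95% of matched lists. ACTA2, TAGLN and the actin-binding gene CALD1 had log2 ratios of -2.35, -1.91 and -1.42, whereas the integrin gene ITGA5, the receptor gene AXL and the metalloproteinase gene MMP14 had ratios of 1.56, 1.53 and 1.51, and TWIST1 stood at 98.96 and 199 FPKM (CALD1, MMP14 and TWIST1 chosen after their values were seen). Epithelial junction and keratin genes had 12 members past the filter and a median of 0.28, within the central 95%. ESRP1 and CLDN7 (2.36 and 9.84 FPKM) were at least 2-fold higher and KRT8 (5.24 and 1.31 FPKM) at least 2-fold lower, while the cadherin gene CDH1 was listed at 0.36 and 0.07 FPKM (KRT8 and CDH1 chosen after their values were seen). With the 6 members at a mean of 5 FPKM or more, the epithelial median was 0.66 at percentile 99.53. The 12 members lay at percentile 89.58, and without ESRP1 their median was 0.18 at percentile 73.91. The 6 members were not recomputed without ESRP1. Wnt and beta-catenin targets had a median of -0.06 over 21 members, with NKD2 at 1.11, APCDD1 at -1.10 and BMP4, chosen after its value was seen, at -2.06. Collagen, laminin and integrin genes had a median of 0.058 over 27 members, which was -0.031 at the same total, with ITGA5 the only member 2-fold apart on FPKM + 1. YAP and TEAD targets had a median of -0.15 over 21 members at percentile 4.06, with a range of 1.08 to 16.95 over 8 alternatives. AXL was at least 2-fold higher, and CCN1, MYOF and AMOTL2 (the last 2 chosen after their values were seen) had ratios of -1.05, -1.39 and -1.10.

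Immediate-early genes had a median of 0.54 over 20 members, above all but 1 of the matched lists. The median was 0.31 with a pseudocount of 5 and also with no filter, still outside the central 95%. JUN (2.64 and 13.34 FPKM), KLF2 (3.39 and 13.82 FPKM) and ATF3 (5.3 and 19.86 FPKM) led, and CCN1 was at least 2-fold lower. Replication-dependent histone genes had a median of 0.85 over 11 members, at percentile 99.98, opposite in sign to the replication list. H2AC6 (3.67 and 14.05 FPKM), H1-2 (17.31 and 47.37 FPKM) and, all at a mean under 5 FPKM, H2BC21, H2AC11 and H4C8 were at least 2-fold higher (H2BC21 and H2AC11 chosen after their values were seen). Most histone members were low, and with a mean of 5 FPKM or more the 5 that remained had a median of 0.45 at percentile 95.96. Interferon-stimulated genes, which a vector or double-stranded RNA can induce, had a median of -0.25 over 21 members at percentile 0.67, and none was 2-fold apart on FPKM + 1. At a mean of 5 FPKM or more this median was -0.095 over 13 genes at percentile 19.94. NF-kB and inflammatory genes had a median of -0.16 over 12 members (0.028 over 24 members with no filter). NRF2 targets had a median of 0.099 over 23 members (-0.014 at the same total). Both lists lay within the central 95%. VCAM1 (10.66 and 25.13 FPKM) in the former and SLC7A11 (7.3 and 24.84 FPKM) and SLC48A1 (4.6 and 12.13 FPKM) in the latter were at least 2-fold higher. Of the markers of other cell types, 4 gastric epithelial lineage genes, 2 leukocyte genes and 10 fibroblast or endothelial genes passed the filter, with medians of 0.086, 0.066 and -0.14, of which the gastric and leukocyte medians were -0.011 and -0.0087 at the same total. The fibroblast-type genes COL3A1 (482.44 and 943.99 FPKM), DCN (68.13 and 140.68 FPKM) and COL1A1 (285.04 and 260.5 FPKM) were expressed in both libraries. In all, 14 of the 31 measured lists lay outside the central 95% of matched lists, 8 lower and 6 higher. About 1.55 would by chance if the genes within a list varied independently. How far genes of a list vary together between cultures was not measured. The count therefore cannot tell whether there is an excess over cultures of the same cells.

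**Figure D3:**
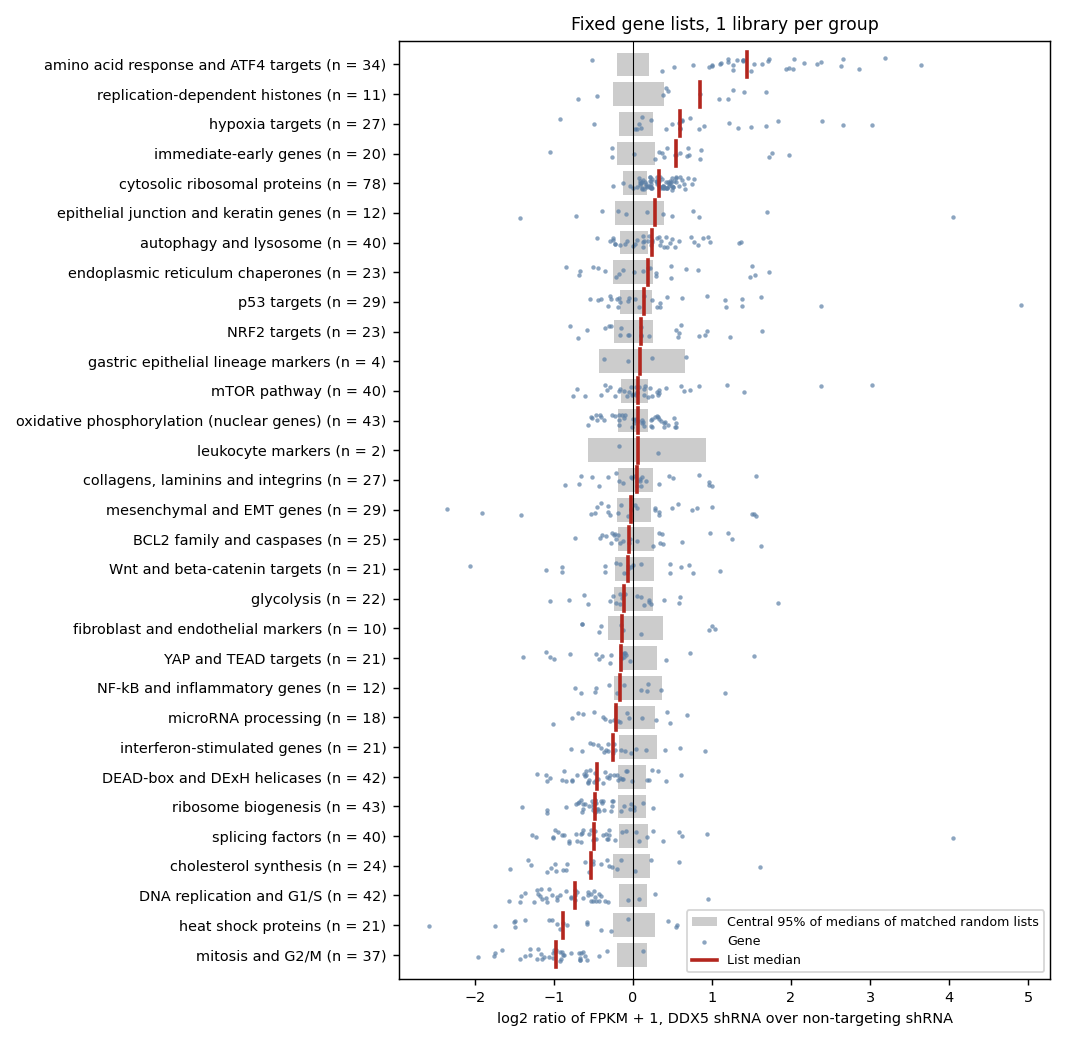
Log2 ratio of FPKM + 1 (x axis, DDX5 shRNA over non-targeting shRNA) for each member (points) of the 31 measured gene lists (y axis), with the list median (red line) and the central 95% of medians of 10000 matched random lists (grey band). The ATF4 target median of 1.44 and the mitosis median of -0.97 lie farthest from their bands in either direction.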

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

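Alternatives were set before the data were examined, except the correction for length and GC content and the lists without members shared with the ATF4 list or without ESRP1, which were chosen after seeing the data. No paired analysis was possible because each condition had 1 library, and no library could be left out for the same reason. Of 1451 values recomputed under an alternative, 1370 moved by less than their spread (or, for counts of genes, by less than 1.5 times), 81 moved by more and 0 changed sign once beyond 2 times their spread. Centring on the median or a trimmed mean subtracts a constant (shifts of -0.024 and -0.0072) smaller than the spreads. The 260 values under each of these settings therefore stayed the same largely by construction. Of the 14 lists outside the central 95%, 12 stayed outside under each of 8 alternatives, the exceptions being the interferon-stimulated and histone lists at a mean of 5 FPKM or more. The centred settings among these cannot change a percentile, so no list could have failed there. Rescaling to the same total applies 1 factor per library and shifts a list and its matched lists nearly alike. It was therefore a weak check as well: the percentile went from 0.67 to 0.62 for interferon-stimulated genes and from 99.28 to 99.51 for autophagy genes. The DDX5 log2 ratio lay between -1.84 and -1.65 under its 5 alternatives, within its spread. The leukocyte list had no member at a mean of 5 FPKM or more. There were 743 genes at least 2-fold higher and 390 genes at least 2-fold lower with a pseudocount of 0.1, and 194 and 102 with 5. Rescaling to the same total shifted the median of all genes by -0.10, and single genes by amounts that depend on their level because of the pseudocount, giving medians of -0.56 for helicases, -0.60 for splicing factors, -0.84 for replication, -1.07 for mitosis, 0.14 for autophagy, -0.038 for the mTOR pathway, -0.13 for EMT genes, -0.59 for ribosome biogenesis, 0.21 for ribosomal proteins, 1.33 for ATF4 targets and -0.047 for oxidative phosphorylation. With a pseudocount of 5 medians were -0.63 for replication, -0.82 for mitosis, 0.42 for hypoxia, 1.28 for ATF4 targets, 0.40 for histones and 0.31 for immediate-early genes, and with 0.1 the histone median was 1.38. With no filter medians were 0.053 for epithelial, 0.028 for NF-kB, -0.11 for interferon-stimulated, 0.45 for histone and 0.31 for immediate-early genes. At a mean of 5 FPKM or more they were 0.31 for p53 targets, 0.66 for epithelial, -0.095 for interferon-stimulated, 0.45 for histone and 0.46 for gastric lineage genes. The gene length trend, a rank correlation of log2 ratio with transcript length across genes, was -0.07 and was -0.082 at a mean of 5 FPKM or more. After correction for length and GC content the ribosomal protein median was 0.23. The cause of these moves was not tested beyond what each setting does by construction. Depth limits genes such as ESRP1 and FGF21, at about 1 and 7 fragments in the non-targeting library.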

Other observations

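Gene groups and genes in this paragraph and the next were chosen after their values were seen, so their direction is not independent evidence. Tubulin genes were lower in the DDX5 shRNA library, with a median log2 ratio of -1.08 over 11 genes, below all 10000 matched lists. TUBB stood at 1339.5 and 533.88 FPKM and TUBA1B at 2368.99 and 982.87 FPKM, while TUBA1A, at 101.17 and 211.15 FPKM, was the only tubulin gene above 0 (it shares 32.6% of its windows with TUBA1B, so their values depend in part on how reads were divided). Caveolae genes had a median of -1.40 over 5 genes. Actin cytoskeleton and smooth-muscle-type genes had a median of -0.54 over 24 genes, with ACTB at 1667.07 and 755.65 FPKM and MYL9 at 37.37 and 11.81 FPKM. Both groups lay below all 10000 matched lists. Chaperonin and prefoldin subunits, which fold actin and tubulin, had a median of -0.45 over 14 genes at percentile 0.45. Nuclear pore genes had a median of -0.44 over 26 genes at percentile 0.02, and proteasome subunits -0.30 over 31 genes at percentile 0.5. Mitochondrial ribosomal proteins had a median of -0.15 over 50 genes at percentile 7.27, which was -0.25 at percentile 1.57 after correction for transcript length and GC content, and fatty acid synthesis genes 0.17 over 10 genes at percentile 81.14.

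Among the tRNA synthetase genes, SARS1 (122.97 and 474.51 FPKM) and WARS1 (89.94 and 406.16 FPKM), members of the fixed ATF4 list, had log2 ratios of 1.94 and 2.16. Cytosolic synthetase genes outside that list had a median of 0.12 over 15 genes at percentile 80.07, among them MARS1 at 0.90, YARS1 at 0.88, IARS1 at 0.82 and KARS1 at -0.32. Synthetase genes for mitochondria had a median of -0.15 over 17 genes at percentile 12.86. Amino acid transporter genes outside the fixed list had a median of 0.34 over 13 genes at percentile 97.27, led by SLC1A4 (3.88 and 27.78 FPKM) and SLC6A9 (11.16 and 56.24 FPKM).

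All tests in the paragraphs that follow except the chromosome medians were chosen after the data were seen, those on length and GC content and on shared list members before their own values were known. The first pattern is the joint difference of ATF4 targets and mitosis genes, whose medians lay 2.41 apart on the log2 scale (spread 0.14). Library scaling is argued against for this gap only, by construction, since a factor per library moves both lists alike. Scaling does bear on each median, which at the same total was 1.33 for ATF4 targets and -1.07 for mitosis. A trend with transcript length and GC content is argued against, because the gap was 2.41 after correction as well. A difference in culture state apart from DDX5, such as density or spent medium, could give amino acid response and lower proliferation together, and with 1 pair of libraries it cannot be told apart from the knockdown or from off-target effects of the shRNA. That DDX5 depletion itself raises the ATF4 program is therefore a hypothesis that these data leave open.

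The second pattern is ESRP1, at 0.02 FPKM in the non-targeting library and 15.92 FPKM in the DDX5 shRNA library. Admixed epithelial cells are argued against, since 13 epithelial genes differed by a median of 0.06 FPKM (quartiles -0.06 and 0.09), with EPCAM at 0.04 and 0.39 FPKM and with CLDN7, 7.48 FPKM higher, and KRT8, at 5.24 and 1.31 FPKM, as exceptions in opposite directions. Reads moved from the paralog ESRP2 are argued against, since ESRP2 stood at only 0.15 and 0.21 FPKM, the sum of both genes was 0.17 and 16.13 FPKM (a ratio of 94.9 over a near-zero level), and 0% of the ESRP1 windows occurred in another gene. Gain or activation of the whole neighbourhood is argued against, since 6 measured neighbours had a median log2 ratio of -0.49, with FSBP (0.11 and 1.93 FPKM) the only one above 0. An insertion of the vector near ESRP1 in an expanded clone and a true induction were not tested, because both need reads or further cultures.

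The third pattern is SERF1A, listed at 0 in the non-targeting library alone. A different division of reads between SERF1A and SERF1B may account for it, since the genes share 97.3% of their windows and their summed FPKM differed by 1.30-fold, from 46.03 to 59.91 FPKM. No biological explanation was tested.

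Without VEGFA and STC2, the members shared with the ATF4 list, the hypoxia median was 0.59 over 25 genes, at percentile 100 of matched lists. After correction for transcript length and GC content the ribosomal protein median was 0.23, from 0.33, at percentile 100 of matched lists. By chromosome, 23 medians ranged from -0.04 (chromosome 15) to 0.08 (chromosome 6). Of these medians, 3 lay outside the central 95% of matched lists, where 1.15 would by chance if genes varied independently.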
